A study of Mus musculus with 10 samples.

How the data were processed

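The deposited tables cover RNA sequencing of brown adipocytes from C57BL/6 mice, 10 libraries in 5 groups of 2: DMSO and BML-260 for 1 and 3 days, and ISO, listed at 1 day. Per the labels, total RNA was taken up in TRIzol and sequenced on Illumina machines. Per the submitters' processing notes the tools were bcl2fastq 2.17.1.14, TopHat2 2.1.1, bedtools and DESeq2 and the builds mm9 and mm10, with no role given for either build. Strandedness, the gene annotation and the counting rule are not given in the sources used here. The table of all genes that the authors deposited holds raw counts per gene symbol, 24640 symbols, each with at least 1 count. In 6 further deposited tables the authors list genes past a threshold, with counts, a log2 fold change, a p-value and an adjusted p-value, per the file headers. Whether that log2 fold change is shrunken is not given in the sources used here. Direction was read from the sign against the deposited counts, and counts of every listed gene with a unique symbol were checked to be identical to the table of all genes. In 26 rows spreadsheet software had turned the symbol into a date, and these hold 0.242% to 0.264% of a library's counts and were kept under the name in the file.

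Samples were grouped by the titles and treatment labels. Totals per library ran from 16955918 to 21185675 counts, and the 10 most abundant genes took 5.46% to 6.58% of them. Counts per library set the precision through counting error, to which the fit adds the spread between libraries: the common dispersion of edgeR was 0.00115, a coefficient of variation of 3.39%. Between the 2 libraries of a group the mean chi-square per gene (1 would be counting error alone) was 1.92 to 3.09 over the 14388 to 14634 genes with at least 20 counts.

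Before the data were examined, the tests, alternatives, named-gene rule and gene lists were fixed. The main test was edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr by group with a minimum count of 10 and a minimum total of 15, which left 15212 genes, a quasi-likelihood fit of 1 mean per group over all 10 libraries (5 residual degrees of freedom) and Benjamini-Hochberg adjustment over genes. A gene with adjusted p under 0.05 is said to have changed or been called. The standard error printed (SE) was derived from this test, as the absolute log2 fold change divided by the square root of its F statistic. The 6 comparisons were BML-260 against DMSO at 1 day and at 3 days, the difference between these effects, ISO against DMSO at 1 day, BML-260 against ISO at 1 day, and DMSO at 3 days against 1 day. CPM used TMM-scaled library sizes, with a prior count of 2 on the log2 scale.

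The 31 gene lists held 558 members, of which 474 were measured. They were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, again with the correlation estimated from the residuals, and with fry, which asks whether a list's genes move 1 way on balance. Fry called 21, 23, 21, 6, 18 and 19 lists in the order of comparisons BML-260 at 1 day, at 3 days, ISO, the difference between times, BML-260 against ISO, and DMSO over time. No list called by camera had a median, mean and test that differed in sign. A count "adjusted over the list alone" adjusts the same p-values over the list's members only. Genes of the lists that mark other cells, such as Acta2, Pdgfra or Fbn1, are also expressed in cultures of adipocytes.

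Named genes follow a rule: in the comparisons of BML-260 at 1 day, BML-260 at 3 days and ISO with DMSO, the 8 higher and 8 lower genes of largest log2 fold change among those called with a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups, passing over predicted loci. In the other comparisons it takes 5 and 5, for each described list up to 4 members of smallest p, and always Ucp1, Ppargc1a, Dio2, Cidea, Adipoq, Fabp4 and Dusp22. Coordinates and exons came from GENCODE M21 on GRCm38 by symbol, where 90.2% of tested genes matched. Of 55 genes named by the rule 16 have exons that overlap those of another gene.

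The fit was tested on simulated data with the groups and depths of these libraries. Of 100 genes changed by 0.5 on the log2 scale the test recovered 96% for BML-260 at 1 day (14954 genes tested), 98% for BML-260 at 3 days (14970), 97% for ISO (14974), 87% for the difference between times (14962), 97% for BML-260 against ISO (14973) and 97% for DMSO over time (14952). Of 100 genes changed by 1 it recovered 100% in each. The changed genes were drawn from those of at least 10 CPM over all libraries, so recovery of less abundant genes was not measured. False calls made up 5.31%, 5.71%, 4.83%, 8.33%, 5.29% and 6.19% of calls in the same order, and camera called 0 or 1 of the 31 unchanged lists. Genes were simulated independently of each other, so this does not tell how often camera calls unchanged lists of correlated genes.

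Alternatives were DESeq2 size factors and upper-quartile scaling, no filter and a filter of at least 10 CPM in 2 libraries, the Wald test of DESeq2 1.42.0, limma-voom, fits of only the groups compared, the replicate number as a block, an adjusted p under 0.01, an absolute log2 fold change of at least 1, DMSO at 3 days as the control of ISO, and each library left out in turn. After the data were seen, DMSO at 3 days was also used for the named genes and lists of ISO, BML-260 at 3 days was set against ISO, and each library's trend with gene length and GC was removed by lowess (span 0.3, 3 iterations) before camera. Replicate numbers were checked for pairing by correlating the deviations from the group means across genes, which gave r of -0.034 to 0.058 over 10 pairs of groups, so that the numbers were not taken to pair libraries. Counting error lowers such r. With the block each comparison called more genes, 2900 against 2727 for BML-260 at 1 day, so a weak shared part is not excluded. For comparisons with shared controls, 20 simulations of unchanged groups gave the correlation that sharing produces. Figures were drawn with matplotlib 3.10.9.

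Of the deposited tables, the lists that pool several groups (1194, 1561, 1412 and 706 genes) were checked for their counts and not used in the comparisons. The 3 lists with ISO were selected on an unadjusted p, and 271, 53 and 61 of their genes have an adjusted p under 0.05 in the deposited values.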

Results

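Messenger RNA levels were read by RNA sequencing in 10 libraries of brown adipocytes from C57BL/6 mice, the fat cells that burn lipid to make heat. The libraries form 5 groups of 2: DMSO, the solvent control, for 1 or 3 days, BML-260, a compound sold as an inhibitor of the phosphatase Dusp22, for 1 or 3 days, and ISO, which the labels do not spell out and list at 1 day. Counts assigned to genes came to 17107063 and 18429606 in the libraries of DMSO at 1 day and to 17094354 and 19232978 in those of BML-260 at 1 day. They came to 16955918 and 21185675 with ISO, to 19296922 and 18938924 with DMSO at 3 days, and to 18458916 and 20039083 with BML-260 at 3 days. After a filter on low counts 15212 genes were tested. Within each group log2 CPM of the 2 libraries correlated across genes with r of at least 0.994. The labels do not say whether 2 libraries of a group come from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical.

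The first principal component of log2 CPM held 41.3% of the variance and the next one 20.1%. On the first component the libraries of DMSO at 1 day lay at -28.6 and -27.3 and those of BML-260 at 1 day at -23.2 and -26.5. The ISO libraries, listed at 1 day, lay at 17.9 and 21.4, on the side of the 3-day libraries of DMSO (5.05 and 4.94) and BML-260 (27.2 and 29.0). On the next component all 4 BML-260 libraries lay between -18.5 and -18.3 and the other 6 between 4.63 and 22.5.

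**Figure D1:**
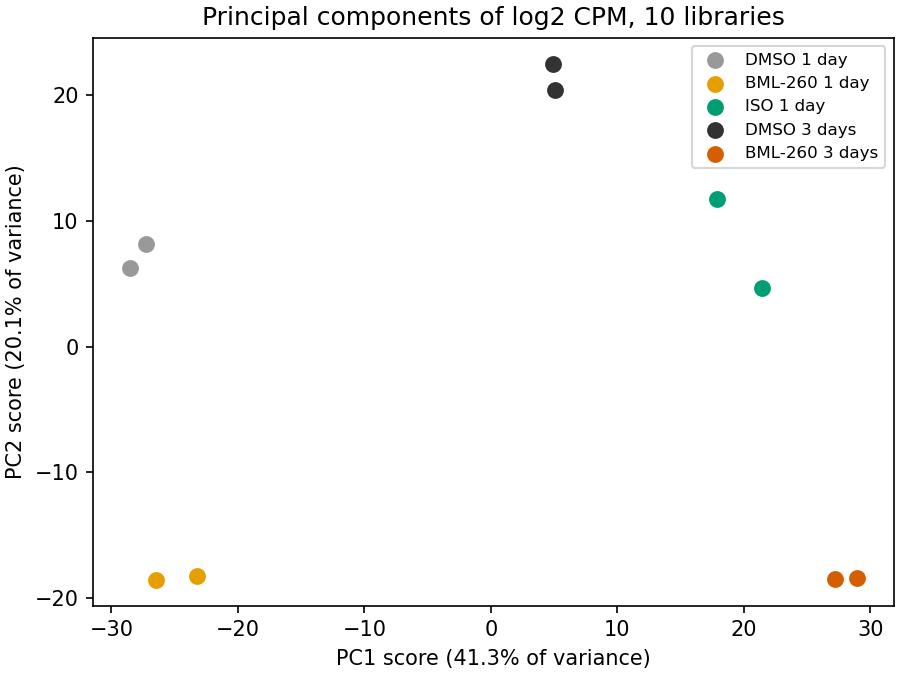
Scores of the 10 libraries on the first 2 principal components of log2 CPM, which hold 41.3% and 20.1% of the variance, 1 point per library coloured by group. The horizontal axis parts the 1-day libraries of DMSO and BML-260 from the 3-day libraries and from ISO, and the vertical axis parts BML-260 from the rest.

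The first comparison asks what BML-260 does within 1 day. Ucp1, the uncoupling protein that lets brown fat make heat, rose from 5.57 ± 0.67 CPM (SD, n = 2) with DMSO to 13.9 ± 2.0 CPM (SD, n = 2) with BML-260. Elovl3, a fatty acid elongase linked to brown fat activity, rose from 10.7 ± 1.5 CPM to 30.5 ± 3.6 CPM (SD, n = 2 each). By edgeR's quasi-likelihood test these were log2 fold changes of 1.32 (SE 0.13, adjusted p = 5.7e-08) and 1.52 (SE 0.11, adjusted p = 1.7e-10), or 2.50-fold and 2.86-fold. In the same libraries Adrb3, the main beta-adrenergic receptor of adipocytes, fell from 19.8 ± 1.2 CPM to 7.76 ± 0.59 CPM, and the oxygen-binding protein myoglobin, Mb, from 193 ± 5.6 CPM to 71.9 ± 6.5 CPM (SD, n = 2 each). Over all genes 2727 changed, 1418 upward and 1309 downward, most of them by little: 98 had an absolute log2 fold change of at least 1, of which 71 fell. The balance over all genes turned to 1216 upward and 1423 downward with upper-quartile scaling, and to 1190 and 1265 with only the groups compared.

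Among genes with at least 10 CPM in the higher group, those most raised at 1 day also included Cbr3, a carbonyl reductase, at 0.97, Acox2, a peroxisomal acyl-CoA oxidase, at 0.89, Kalrn at 0.87, Extl1 at 0.80 and the stress-induced transcription factor Atf3 at 0.80 on the log2 scale. The signal recognition particle RNA row Metazoa_SRP, at 1.13, rested on 1 library: without BML-260 1 day replicate 2 it came to 0.34 (edgeR adjusted p = 0.37). Among the genes that fell, Hp, the plasma protein haptoglobin, was at -1.43 (SE 0.07), Apcdd1 at -1.33, Sncg, a synuclein abundant in adipocytes, at -1.33, Prtn3 at -1.19 and Adam11 at -1.13. The mitochondrial cysteine transfer RNA mt-Tc fell by 1.60, but without DMSO 1 day replicate 1 it was at -0.53 (edgeR adjusted p = 0.070). Fabp4, the fatty acid binding protein of adipocytes, rose by 0.71 (SE 0.04), Cidea, a lipid droplet protein of brown fat, rose by 0.27, and the adipocyte hormone Adipoq fell by 0.35. Without BML-260 1 day replicate 2 the rise of Cidea was 0.16 and did not pass (edgeR adjusted p = 0.085). Ppargc1a, a coactivator that drives mitochondrial genes, stood at 0.01 (adjusted p = 0.92) and Dusp22 itself at 0.07 (adjusted p = 0.47) by edgeR's test. Dio2, the thyroid hormone deiodinase of active brown fat, had at most 2 counts in any library and was not tested. Ucp1 lies on chromosome 8 from 83290352 to 83298452 and Dusp22 on chromosome 13 from 30659999 to 30711231 (GRCm38, GENCODE M21).

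At 1 day, of 45 nuclear genes of oxidative phosphorylation (OXPHOS), the respiratory chain and ATP synthase, 26 rose, 0 fell and 19 did not pass (29 rose adjusted over the list alone), with a median log2 fold change of 0.14 and Uqcrc2 at 0.31 and Cycs at 0.35. Camera, which asks whether a list moved against the other genes, gave adjusted p = 5.7e-09, and adjusted p = 0.19 with an estimated correlation. Of 22 fatty acid oxidation genes 17 rose and 0 fell (19 rose adjusted over the list alone). Hadha was at 0.43 and Decr1 at 0.41, with a list median of 0.21 (for the list camera adjusted p = 3.7e-09, and adjusted p = 0.17 with an estimated correlation). Among PPAR targets 7 of 14 rose and 1 fell (8 and 1 adjusted over the list alone). Plin2, a lipid droplet coat protein, was at 0.45 (for the list camera adjusted p = 0.00094, and adjusted p = 0.15 with an estimated correlation). Of 17 glycolysis genes 9 rose and 0 fell (10 and 0 adjusted over the list alone). Gpi1 was at 0.33 (for the list camera adjusted p = 0.0045, and adjusted p = 0.43 with an estimated correlation).

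Of 20 measured targets of NRF2, the transcription factor of the oxidative stress response, 17 rose and 0 fell (17 and 0 adjusted over the list alone). Hmox1, heme oxygenase, was at 0.62 and Srxn1, sulfiredoxin, at 0.57, with a list median of 0.29 (for the list camera adjusted p = 8e-12, and adjusted p = 0.064 with an estimated correlation). The ATF4 stress response list, on amino acid supply and integrated stress, had 14 of 21 genes rise and 0 fall (15 and 0 adjusted over the list alone). Ddit3 was at 0.47 and Asns at 0.36 (for the list camera adjusted p = 1e-07, and adjusted p = 0.15 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum (ER), rose by 0.49, and 4 of 17 ER chaperone genes rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.18 with an estimated correlation). For hypoxia genes the counts were 6 up and 0 down of 14 (8 and 1 adjusted over the list alone). Ero1l was at 0.56 and Ndrg1 at 0.45 (for the list camera adjusted p = 0.0045, and adjusted p = 0.15 with an estimated correlation). Cholesterol synthesis genes (6 of 19 rose and 0 fell; 6 and 1 adjusted over the list alone; Sqle at 0.47) and p53 targets (4 of 16 rose and 1 fell; 6 and 2 adjusted over the list alone; Gadd45a at 0.57) were called more weakly. Their camera adjusted p-values were 0.021 and 0.036, with adjusted p = 0.51 and adjusted p = 0.17 with an estimated correlation, and each call was lost in some fits that left out 1 library.

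At 1 day 21 of the 23 measured extracellular matrix genes fell and 0 rose (21 and 0 adjusted over the list alone). Fibronectin, Fn1, was at -0.77, the collagen Col5a1 at -0.57 and the collagen cross-linking enzyme Lox at -0.52 (list median -0.44, camera adjusted p = 1e-14, and adjusted p = 0.17 with an estimated correlation). Preadipocyte and fibroblast markers fell in 6 of 11 cases and rose in 0 (6 and 0 adjusted over the list alone). Sfrp2 was at -1.10, Fbn1, fibrillin, at -0.76 and Dlk1, a marker of preadipocytes, at -0.79 (for the list camera adjusted p = 6.9e-06, and adjusted p = 0.15 with an estimated correlation). Smooth muscle and pericyte markers fell in 6 of 9 cases and rose in 0 (7 and 0 adjusted over the list alone). The smooth muscle actin Acta2 was at -0.79 and Tagln at -0.69 (for the list camera adjusted p = 1.1e-05, and adjusted p = 0.15 with an estimated correlation). Of 24 proliferation genes 15 fell and 0 rose (18 and 0 adjusted over the list alone). Mki67 was at -0.27 and Mcm5 at -0.27 (for the list camera adjusted p = 6.3e-08, and adjusted p = 0.15 with an estimated correlation).

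Adipocyte identity genes were split at 1 day: 10 of 20 fell and 5 rose (11 and 5 adjusted over the list alone). Sncg and Adrb3 fell, Acvr1c was at -0.63 and Fabp4 rose (list median -0.18, camera adjusted p = 0.0082, and adjusted p = 0.48 with an estimated correlation). STAT3 targets fell in 8 of 18 cases and rose in 1 (8 and 1 adjusted over the list alone). Lrg1 was at -0.59 beside Hp (for the list camera adjusted p = 0.00044, and adjusted p = 0.15 with an estimated correlation). White adipocyte genes fell in 2 of 10 cases and rose in 0 (2 and 0 adjusted over the list alone), namely the hormone leptin, Lep, at -2.00 and angiotensinogen, Agt, at -0.52 (camera adjusted p = 0.029, and adjusted p = 0.19 with an estimated correlation). All 3 measured mitochondrially encoded genes of 13 fixed ones fell (3 adjusted over the list alone). The gene mt-Nd3 was at -0.79 (for the list camera adjusted p = 0.019, and adjusted p = 0.20 with an estimated correlation). For interferon-stimulated genes 1 of 21 fell and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.019, and adjusted p = 0.52 with an estimated correlation). The calls of the last 3 lists were each lost when 1 library of BML-260 or DMSO at 1 day was left out.

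The remaining 12 lists were not called at 1 day. Of the 17 measured brown thermogenic genes 4 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.53), with Ppara at 0.35 and Kcnk3 at -0.41 beside Ucp1 and Elovl3. The cAMP and CREB early targets had 2 genes up and 6 down of 19 (2 and 6 adjusted over the list alone; camera adjusted p = 0.074), and the NF-kB inflammatory genes had 1 up and 5 down of 15 (1 and 6 adjusted over the list alone; camera adjusted p = 0.084), with the chemokine Ccl2 at -0.99. Lipogenesis genes had 1 up and 6 down of 17 (2 and 7 adjusted over the list alone; Fasn, fatty acid synthase, at -0.39; camera adjusted p = 0.12), and lipolysis genes 3 up and 3 down of 10 (3 and 3 adjusted over the list alone; camera adjusted p = 0.98). Heat shock genes had 4 up and 3 down of 14 (5 and 3 adjusted over the list alone; camera adjusted p = 0.67), aryl hydrocarbon receptor targets 1 up and 2 down of 5 (1 and 2 adjusted over the list alone; camera adjusted p = 0.53), and dual-specificity phosphatases 1 up and 1 down of 18 (1 and 0 adjusted over the list alone; camera adjusted p = 0.77). No gene passed the test among 4 measured beige adipocyte markers (camera adjusted p = 0.37), 4 endothelial markers (adjusted p = 0.82), 3 macrophage markers (adjusted p = 0.69) and 4 muscle markers (adjusted p = 0.82), over all genes or adjusted over the list alone.

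With the estimated correlation between genes camera called 0 of the 31 lists at 1 day, and 8 lists had an unadjusted p under 0.05. The count of changed genes depended on single libraries: it was 1262 without DMSO 1 day replicate 2, 1733 without BML-260 1 day replicate 1 and 1804 without BML-260 1 day replicate 2, and DESeq2 called 1746. Exons of Elovl3, Adrb3, Mb and Prtn3 overlap annotated exons of other genes, whose reads the counts may include. The authors' deposited list for this comparison holds 592 genes with a positive and 544 with a negative fold change. Of the genes in that deposited list edgeR called 1132 in the same direction and 0 in the opposite one. That deposited list gives log2 fold changes of 0.80 for Ucp1 and -1.33 for Mb.

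**Figure D2:**
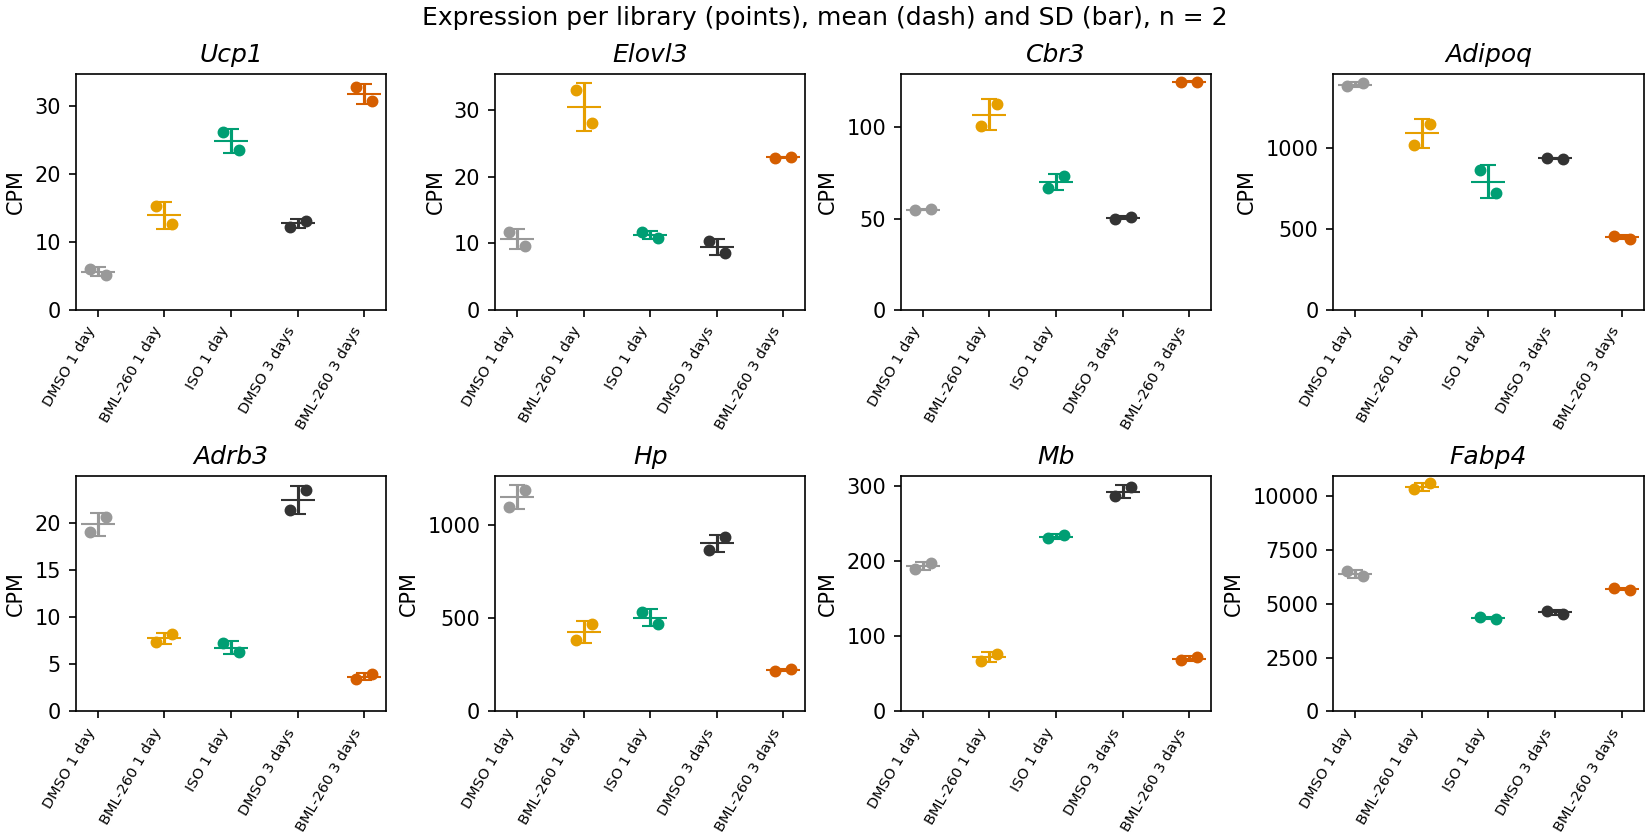
CPM of 8 genes in each library, 2 points per group with the group mean (dash) and SD (bar). With BML-260 Ucp1, Elovl3 and Cbr3 stand above the DMSO libraries of the same time and Adrb3, Hp and Mb below them, while Adipoq reaches 448 ± 14 CPM at 3 days against 936 ± 2.1 CPM with DMSO (SD, n = 2 each).

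The effect of BML-260 was then measured at 3 days, against DMSO of the same time. Ucp1 rose from 12.7 ± 0.63 CPM to 31.7 ± 1.5 CPM (SD, n = 2 each), a log2 fold change of 1.32 (SE 0.10, edgeR adjusted p = 4.5e-11), or 2.50-fold. Adrb3 fell from 22.4 ± 1.5 CPM to 3.66 ± 0.37 CPM (SD, n = 2 each), a log2 fold change of -2.61 (SE 0.13, edgeR adjusted p = 1.6e-14). Adipoq fell by 1.06 (SE 0.06), from 936 ± 2.1 CPM to 448 ± 14 CPM (SD, n = 2 each), and Mb and Hp fell to log2 fold changes of -2.05 (SE 0.06) and -2.02 (SE 0.07). In all 5407 genes changed, 2624 upward and 2783 downward, and of the 437 with an absolute log2 fold change of at least 1, 330 fell. The balance over all genes turned to 2957 upward and 2518 downward with DESeq2's size factors, and was 2077 and 3313 with upper-quartile scaling.

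Among genes with at least 10 CPM in the higher group, those most raised at 3 days by the naming rule were Atf3 at 1.66 (SE 0.10), Ghrh, a growth hormone-releasing hormone, at 1.58, Extl1 at 1.47, the glutathione transferase Gsta3 at 1.43, Acox2 at 1.40, Ucp1, Cbr3 at 1.31 and the integrin Itgad at 1.31. Under the same limit those most lowered were Adrb3, C4b, a complement component, at -2.34 (SE 0.15), Mb, Hp, Ccl2 at -1.85, Prtn3 at -1.83, the small GTPase Rasd1 at -1.77 and the hormone resistin, Retn, at -1.67. Fabp4 rose by 0.31 and Cidea by 0.24, whereas Ppargc1a fell by 0.28 (SE 0.06, edgeR adjusted p = 0.00082). Dusp22 stood at -0.06 (SE 0.06, edgeR adjusted p = 0.47). Exons of Itgad, Adrb3, Mb and Prtn3 overlap annotated exons of other genes, which for Itgad include Cox6a2. Their counts may include reads of those genes.

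Adipocyte identity genes fell as a group at 3 days: 15 of 20 fell and 3 rose (16 and 3 adjusted over the list alone), with a median of -0.83. Acvr1c was at -1.33, the carbonic anhydrase Car3 at -1.23 and adipsin, Cfd, at -1.03. For the list camera gave adjusted p = 5.9e-07, with adjusted p = 0.27 with an estimated correlation. Markers of other cells fell beside them: 9 of 11 preadipocyte and fibroblast markers (10 adjusted over the list alone), with Fbn1 at -0.99 and Pdgfrb at -0.59, and 7 of 9 smooth muscle and pericyte markers (7 adjusted over the list alone), with Acta2 at -1.26 and Mcam at -1.09, while 0 rose in either list over all genes. Camera gave these adjusted p = 1.3e-05 and 0.00011, with adjusted p = 0.13 and adjusted p = 0.17 with an estimated correlation. Extracellular matrix genes fell in 17 of 23 cases and rose in 0 (18 and 0 adjusted over the list alone). Tnc was at -0.89 and the matrix protein Thbs1 at -0.77 (for the list camera adjusted p = 5.9e-07, and adjusted p = 0.31 with an estimated correlation). White adipocyte genes fell in 5 of 10 cases (5 adjusted over the list alone), with Lep at -3.24 (camera adjusted p = 0.026, and adjusted p = 0.27 with an estimated correlation). Of the beige adipocyte markers P2rx5 fell by 0.45 and Slc36a2 fell by 0.18 and 0 rose (2 fell adjusted over the list alone; camera adjusted p = 0.42).

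At 3 days interferon-stimulated genes fell in 14 of 21 cases and rose in 0 (17 and 1 adjusted over the list alone). Usp18 was at -1.70 and Ifit3 at -0.92 (for the list camera adjusted p = 0.001, and adjusted p = 0.38 with an estimated correlation). NF-kB inflammatory genes fell in 8 of 15 cases and rose in 2 (9 and 2 adjusted over the list alone). The chemokine Ccl7 was at -1.02 (for the list camera adjusted p = 0.0067, and adjusted p = 0.13 with an estimated correlation). STAT3 targets fell in 10 of 18 cases and rose in 4 (10 and 4 adjusted over the list alone). Steap4 was at -1.22 (for the list camera adjusted p = 0.034, and adjusted p = 0.27 with an estimated correlation), a call lost with upper-quartile scaling (camera adjusted p = 0.054). Of the 3 measured mitochondrially encoded genes 2 fell (3 adjusted over the list alone), mt-Co3 at -0.80 and mt-Nd3 at -0.84 (camera adjusted p = 0.030, and adjusted p = 0.27 with an estimated correlation).

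At 3 days, of 19 cholesterol synthesis genes 16 rose and 0 fell (16 and 1 adjusted over the list alone). Squalene epoxidase, Sqle, was at 1.02 and Mvd at 0.89 (list median 0.26, camera adjusted p = 2.3e-06, and adjusted p = 0.27 with an estimated correlation). The ER chaperone genes rose in 12 of 17 cases and fell in 0 (13 and 0 adjusted over the list alone), Hspa5 by 0.89 and Hyou1 by 0.56 (camera adjusted p = 3.5e-06, and adjusted p = 0.13 with an estimated correlation). The ATF4 stress response genes rose in 16 of 21 cases and fell in 1 (17 and 2 adjusted over the list alone), Ddit3 by 0.65 and Aldh1l2 by 0.74 (camera adjusted p = 2.5e-07, and adjusted p = 0.13 with an estimated correlation). NRF2 targets rose in 14 of 20 cases and fell in 1 (16 and 1 adjusted over the list alone), Hmox1 by 0.94 (camera adjusted p = 2.2e-07, and adjusted p = 0.13 with an estimated correlation). Glycolysis genes rose in 12 of 17 cases and fell in 1 (12 and 2 adjusted over the list alone). Gpi1 was at 0.66 and the glucose transporter Slc2a1 at 0.60 (for the list camera adjusted p = 1.3e-05, and adjusted p = 0.27 with an estimated correlation). The OXPHOS genes rose in 28 of 45 cases and fell in 1 (29 and 1 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 2.2e-07, and adjusted p = 0.27 with an estimated correlation). For hypoxia genes the counts were 9 up and 1 down of 14 (9 and 2 adjusted over the list alone), with Ndrg1 at 1.16, and for p53 targets 10 up and 1 down of 16 (10 and 2 adjusted over the list alone), with Gadd45a at 0.88. Camera gave these adjusted p = 0.0018 and 0.0061, with adjusted p = 0.13 with an estimated correlation for each.

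Other lists were not called at 3 days: fatty acid oxidation genes had 8 up and 3 down of 22 (8 and 3 adjusted over the list alone; camera adjusted p = 0.13), PPAR targets 8 up and 3 down of 14 (8 and 3 adjusted over the list alone; camera adjusted p = 0.099) and brown thermogenic genes 3 up and 5 down of 17 (3 and 7 adjusted over the list alone; camera adjusted p = 0.58). The dual-specificity phosphatases had 6 up and 4 down of 18 (6 and 5 adjusted over the list alone; camera adjusted p = 0.46), with Dusp8 at 1.09 and Dusp1 at -0.49. Proliferation genes, which had fallen at 1 day, were not called at 3 days either. With the estimated correlation camera called 0 of the 31 lists and 8 had an unadjusted p under 0.05. The authors' deposited list for 3 days holds 1838 genes with a positive and 1347 with a negative fold change. Of the genes in that deposited list edgeR called 3156 in the same direction and 0 in the opposite one, and the deposited list gives Adrb3 a log2 fold change of -2.07.

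The next comparison asks whether the response to BML-260 is the same at both times, whose libraries are all different. Across the 15212 genes the log2 fold changes at 1 and 3 days correlated with Pearson's r of 0.425 and Spearman's rho of 0.440, and genes are not independent replicates. Both comparisons called 897 genes upward, with 245 expected under independence, and 849 downward, with 239 expected. These expected counts give every gene the same chance of being called, whatever its abundance. Of the 1796 genes called at both times, 97.2% moved the same way, and 50 moved in opposite directions. Of the genes called at 1 day, 64.0% were called in the same direction at 3 days.

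**Figure D3:**
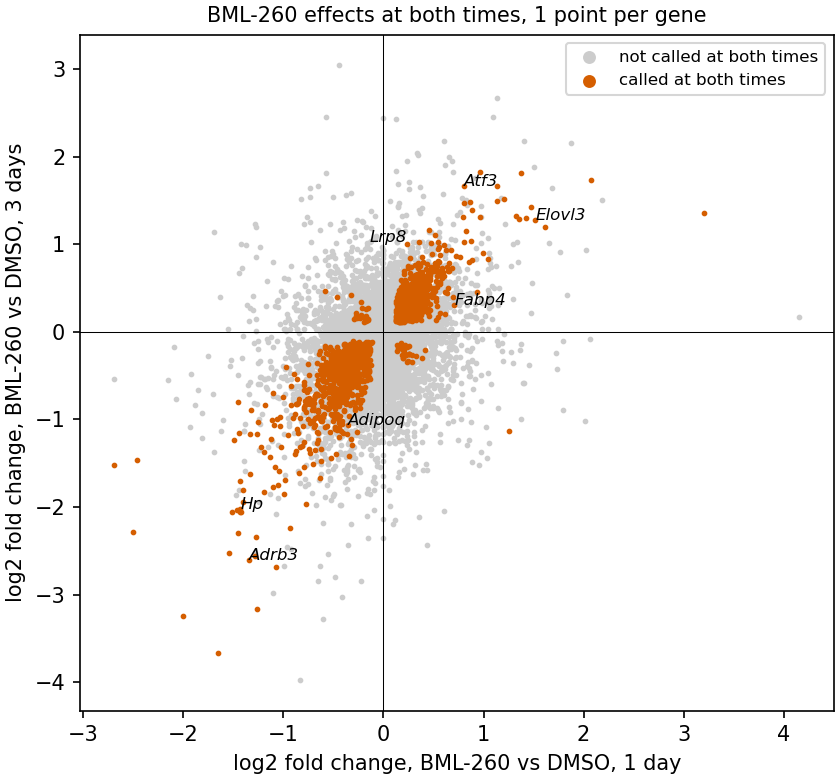
Log2 fold change of each of the 15212 tested genes with BML-260 against DMSO at 1 day (horizontal axis) and at 3 days (vertical axis), with the 1796 genes called at both times in orange. Most orange points lie in the lower left and upper right fields, 849 and 897 genes, and 50 lie in the others.

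The difference between the 2 responses, tested as an interaction, was past the threshold for 1287 genes, 598 with a more positive and 689 with a more negative effect at 3 days. This balance turned with the scaling, to 731 and 624 with DESeq2's size factors. For 1055 of these the change was of larger size at 3 days. The effect was more positive at 3 days for Lrp8, a lipoprotein receptor family member (difference 1.16, SE 0.23), Ghrh (0.98), the phosphatase Pgp (0.97), Dusp8 (0.91) and Scand1 (0.87), and more negative for Adrb3 (-1.26, SE 0.18, edgeR adjusted p = 8.1e-05), Metazoa_SRP (-1.24), the transcription factor Prox1 (-1.08), C4b (-1.07) and Retn (-1.03). Scand1 was called at both times in opposite directions, at -0.46 and 0.40. Pgp and Lrp8 were not called at 1 day (edgeR adjusted p = 0.0549 and 0.683) and rose at 3 days, by 0.66 and 1.03. Without DMSO 1 day replicate 2 the differences of Ghrh and Dusp8 no longer passed (edgeR adjusted p = 0.175 and 0.0586), and that of Metazoa_SRP, at adjusted p = 0.046, was lost in most fits that left out 1 library.

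Adipocyte identity genes had the clearest shift between the times: the effect was more negative at 3 days for 15 of 20 and more positive for 1 (16 and 1 adjusted over the list alone). Aqp7, a glycerol channel, was at -0.81 and Adipoq at -0.71 (for the list camera adjusted p = 4.4e-08, and adjusted p = 0.49 with an estimated correlation). Fatty acid oxidation genes had 8 more negative and 0 more positive of 22 (11 and 0 adjusted over the list alone). Acadm was at -0.30 (for the list camera adjusted p = 0.00032, and adjusted p = 0.49 with an estimated correlation). The effect was more positive for 10 of 17 glycolysis genes and more negative for 1 (10 and 1 adjusted over the list alone), with Hk2 at 0.41, and more positive for 5 of 19 cholesterol synthesis genes and more negative for 0 (7 and 0 adjusted over the list alone), with the regulator Srebf2 at 0.54. Each had camera adjusted p = 0.00022, and adjusted p = 0.49 with an estimated correlation. Proliferation genes (4 more positive and 0 more negative of 24; 4 and 0 adjusted over the list alone; Plk1 at 0.46), ER chaperone genes (4 and 0 of 17; 6 and 0 adjusted over the list alone; Hyou1 at 0.46) and ATF4 stress response genes (3 and 1 of 21; 12 and 2 adjusted over the list alone; Gdf15 at 0.67) completed the 7 lists called. Their camera adjusted p-values were 7e-04, 0.0021 and 0.0047, each with adjusted p = 0.49 with an estimated correlation, and the ATF4 call was lost without BML-260 3 days replicate 1. With the estimated correlation camera called 0 of 31 lists and 0 had an unadjusted p under 0.05. The number of genes fell to 661 without DMSO 3 days replicate 1, 784 without DMSO 3 days replicate 2, 670 without DMSO 1 day replicate 2 and 769 without BML-260 3 days replicate 1, and DESeq2 called 721.

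What is called time in culture here was measured with DMSO alone, 3 days against 1 day. The age of the cultures at collection is not given in the sources used here. Extracellular matrix genes rose over this time, with Col1a1, a chain of the main fibrillar collagen, at 1.00 (SE 0.06) and Postn, periostin, at 1.06 (SE 0.06). Fasn was at -0.89 (SE 0.05) and Gpd1, glycerol-3-phosphate dehydrogenase, at -1.34 (SE 0.05). Gpd1 went from 1500 ± 16 CPM to 591 ± 2.3 CPM and Ucp1 from 5.57 ± 0.67 CPM to 12.7 ± 0.63 CPM (SD, n = 2 each). By edgeR's test 5315 genes changed, 2755 upward and 2560 downward, and 249 had an absolute log2 fold change of at least 1. The balance turned to 2409 upward and 2844 downward with upper-quartile scaling, and to 2721 and 2827 with only the groups compared. With the limit of 10 CPM in the higher group, the genes most raised were the matrix metalloproteinase Mmp11 at 1.84, Pik3ip1 at 1.61, the clock repressor Nr1d1 at 1.60, the collagen receptor Itga11 at 1.60 and Tfap4 at 1.52. Those most lowered were mt-Tc at -2.11 (-1.04 without DMSO 1 day replicate 1), the lipolysis inhibitor G0s2 at -1.51, Osgin1 at -1.50, Gpd1 and Nat8l, an acetyltransferase enriched in brown fat, at -1.31. Exons of Mmp11, Pik3ip1, Nr1d1 and Gpd1 overlap annotated exons of other genes, which for Mmp11 means Chchd10, and their counts may include those reads.

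Camera called 12 lists for DMSO over time with its preset correlation, not all of which are described here. Of the 23 extracellular matrix genes 22 rose over time and 0 fell (22 and 0 adjusted over the list alone; camera adjusted p = 3.4e-13, and adjusted p = 0.32 with an estimated correlation). Hypoxia genes rose in 13 of 14 cases and fell in 1 (13 and 1 adjusted over the list alone). Kdm3a was at 0.91 (for the list camera adjusted p = 4.8e-07, and adjusted p = 0.15 with an estimated correlation). Fibroblast and preadipocyte markers rose in 7 of 11 cases and fell in 2 (7 and 2 adjusted over the list alone). Pdgfra was at 0.98 (for the list camera adjusted p = 0.015, and adjusted p = 0.32 with an estimated correlation). OXPHOS genes fell in 43 of 45 cases and rose in 0 (44 and 0 adjusted over the list alone). Cycs was at -0.72 and Ndufa4 at -0.65 (list median -0.42, camera adjusted p = 5.8e-23, and adjusted p = 0.24 with an estimated correlation). Fatty acid oxidation genes fell in 17 of 22 cases and rose in 1 (17 and 1 adjusted over the list alone). Hadha was at -0.55 (for the list camera adjusted p = 2.4e-07, and adjusted p = 0.32 with an estimated correlation). Adipocyte identity genes fell in 14 of 20 cases and rose in 4 (15 and 4 adjusted over the list alone). The transcription factor Cebpa was at -0.85 (for the list camera adjusted p = 0.00041, and adjusted p = 0.41 with an estimated correlation), and lipogenesis genes fell in 10 of 17 cases and rose in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.32 with an estimated correlation). ER chaperone genes rose in 12 of 17 cases and fell in 0 (12 and 0 adjusted over the list alone). Hspa5 was at 0.42 (for the list camera adjusted p = 3e-05, and adjusted p = 0.24 with an estimated correlation). With the estimated correlation camera called 0 of 31 lists, and 4 had an unadjusted p under 0.05. Log2 fold changes over this time correlated with gene length at Spearman's rho of 0.253, across 13725 genes. With the length and GC trends removed camera called 11 lists. The list medians given here are those before the removal.

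The comparison of ISO with DMSO at 1 day asks what ISO does at the time the labels list for it. Ucp1 rose from 5.57 ± 0.67 CPM to 24.8 ± 1.8 CPM (SD, n = 2 each), a log2 fold change of 2.15 (SE 0.12, edgeR adjusted p = 1.9e-13), or 4.44-fold. Prg4, a lubricating proteoglycan, rose by 3.07 (SE 0.18) and Nr1d1 by 2.18 (SE 0.12), while G0s2 fell by 1.57 (SE 0.08) and Adrb3 fell by 1.56 (SE 0.12). With 6339 genes changed, 3255 upward and 3084 downward, ISO differed from DMSO at 1 day in more genes than BML-260 did, and 573 had an absolute log2 fold change of at least 1. With upper-quartile scaling the balance turned, to 2588 upward and 3831 downward. The libraries of ISO stood on the side of the 3-day libraries on the first component, and against DMSO at 3 days 3027 genes differed, 1620 upward and 1407 downward.

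Also among the genes most raised with ISO, of those with at least 10 CPM in the higher group, were the clock genes Per1 at 1.60 and Bhlhe41 at 1.57, the carbonic anhydrase Car9 at 1.58, the collagen Col3a1 at 1.58 and Itga11 at 1.55. The most lowered included mt-Tc at -2.42 (-1.34 without DMSO 1 day replicate 1), Osgin1 at -1.54, Adamts15 at -1.50, Trmt12 at -1.47, Itih4 at -1.47 and Gpd1 at -1.37. Adipoq fell by 0.81, Fabp4 fell by 0.56 and Ppargc1a fell by 0.50, Cidea rose by 0.27, and Dusp22 stood at -0.03 (SE 0.06, edgeR adjusted p = 0.75). Against DMSO at 3 days Fabp4 stood at -0.08 (edgeR adjusted p = 0.157), and Cidea and Itga11 turned to -0.36 and -0.05. Ucp1 was at 0.96, Prg4 at 2.40, Nr1d1 at 0.58 and Per1 at 0.51. Under that control 6 of the 8 most lowered genes were not called: G0s2 stood at -0.06, Osgin1 at -0.03, Gpd1 at -0.03, Itih4 at -0.16, Adamts15 at -0.25 and mt-Tc at -0.31.

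With ISO 43 of 45 OXPHOS genes fell and 0 rose (43 and 0 adjusted over the list alone). Ndufa4 was at -0.75 (list median -0.41, camera adjusted p = 2.7e-18, and adjusted p = 0.25 with an estimated correlation). Extracellular matrix genes rose in 22 of 23 cases and fell in 1 (22 and 1 adjusted over the list alone). Col1a1 was at 1.25 (list median 0.69, camera adjusted p = 2.6e-11, and adjusted p = 0.30 with an estimated correlation). Against DMSO at 3 days neither was called: the OXPHOS genes had a median of -0.01 (camera adjusted p = 0.70) and the matrix genes of 0.09 (camera adjusted p = 0.18). Fatty acid oxidation genes fell in 18 of 22 cases and rose in 1 (18 and 1 adjusted over the list alone; Hadhb at -0.78; camera adjusted p = 6.8e-07, and adjusted p = 0.30 with an estimated correlation), again with no call against DMSO at 3 days (median -0.07; camera adjusted p = 0.24). Hypoxia genes rose in 12 of 14 cases and fell in 1 (12 and 1 adjusted over the list alone). Pfkfb3 was at 1.52 and Ndrg1 at 1.18 (list median 0.68, camera adjusted p = 1.3e-06, and adjusted p = 0.18 with an estimated correlation). ER chaperone genes rose in 16 of 17 cases and fell in 0 (16 and 0 adjusted over the list alone). Hspa5 was at 0.86 (list median 0.31, camera adjusted p = 1.7e-07, and adjusted p = 0.22 with an estimated correlation). Both kept a call against DMSO at 3 days, with medians of 0.21 and 0.17 (camera adjusted p = 0.018 and 0.0012, and adjusted p = 0.40 with an estimated correlation for each).

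Adipocyte identity genes fell in 15 of 20 cases with ISO and rose in 2 (16 and 2 adjusted over the list alone). Cfd was at -1.18 and Cebpa at -1.05 (for the list camera adjusted p = 1.5e-05, and adjusted p = 0.30 with an estimated correlation). Against DMSO at 3 days the list kept its call with the preset correlation but not with an estimated one, and these members differed less. Cfd was at 262 ± 14 CPM with ISO and 364 ± 18 CPM with DMSO at 3 days, and Cebpa at 183 ± 5.2 CPM and 211 ± 11 CPM (SD, n = 2 each). Preadipocyte and fibroblast markers rose in 7 of 11 cases and fell in 2 (7 and 2 adjusted over the list alone), with the mesenchymal surface protein Ly6a at 1.36, and STAT3 targets rose in 9 of 18 cases and fell in 3 (10 and 3 adjusted over the list alone), with Lcn2 at 1.12. All 3 mitochondrially encoded genes fell (3 adjusted over the list alone), with mt-Nd3 at -1.17, and each of these last 3 lists had camera adjusted p = 0.026, and adjusted p = 0.30 with an estimated correlation. Against DMSO at 3 days none of the 3 was called (camera adjusted p = 0.53 for the fibroblast markers, 0.53 for STAT3 targets and 0.061 for the mitochondrially encoded genes), and the median of the fibroblast markers turned to -0.14. The cAMP and CREB early targets were not called, with 8 up and 4 down of 19 (8 and 4 adjusted over the list alone; camera adjusted p = 0.11), among them Per1 and the kinase Sik1 at 0.99. Brown thermogenic genes were not called either, with 2 up and 7 down of 17 (2 and 7 adjusted over the list alone; camera adjusted p = 0.15), and against DMSO at 3 days they were called downward, with 1 up and 7 down (median -0.23; camera adjusted p = 0.020, and adjusted p = 0.40 with an estimated correlation). With the estimated correlation camera called 0 of 31 lists for ISO against DMSO at 1 day, and 3 had an unadjusted p under 0.05. In that comparison log2 fold changes correlated with gene length at Spearman's rho of 0.156. With the length and GC trends removed camera called 7 lists. Exons of Prg4, Nr1d1, Car9, Gpd1 and Adrb3 overlap annotated exons of other genes.

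**Figure D4:**
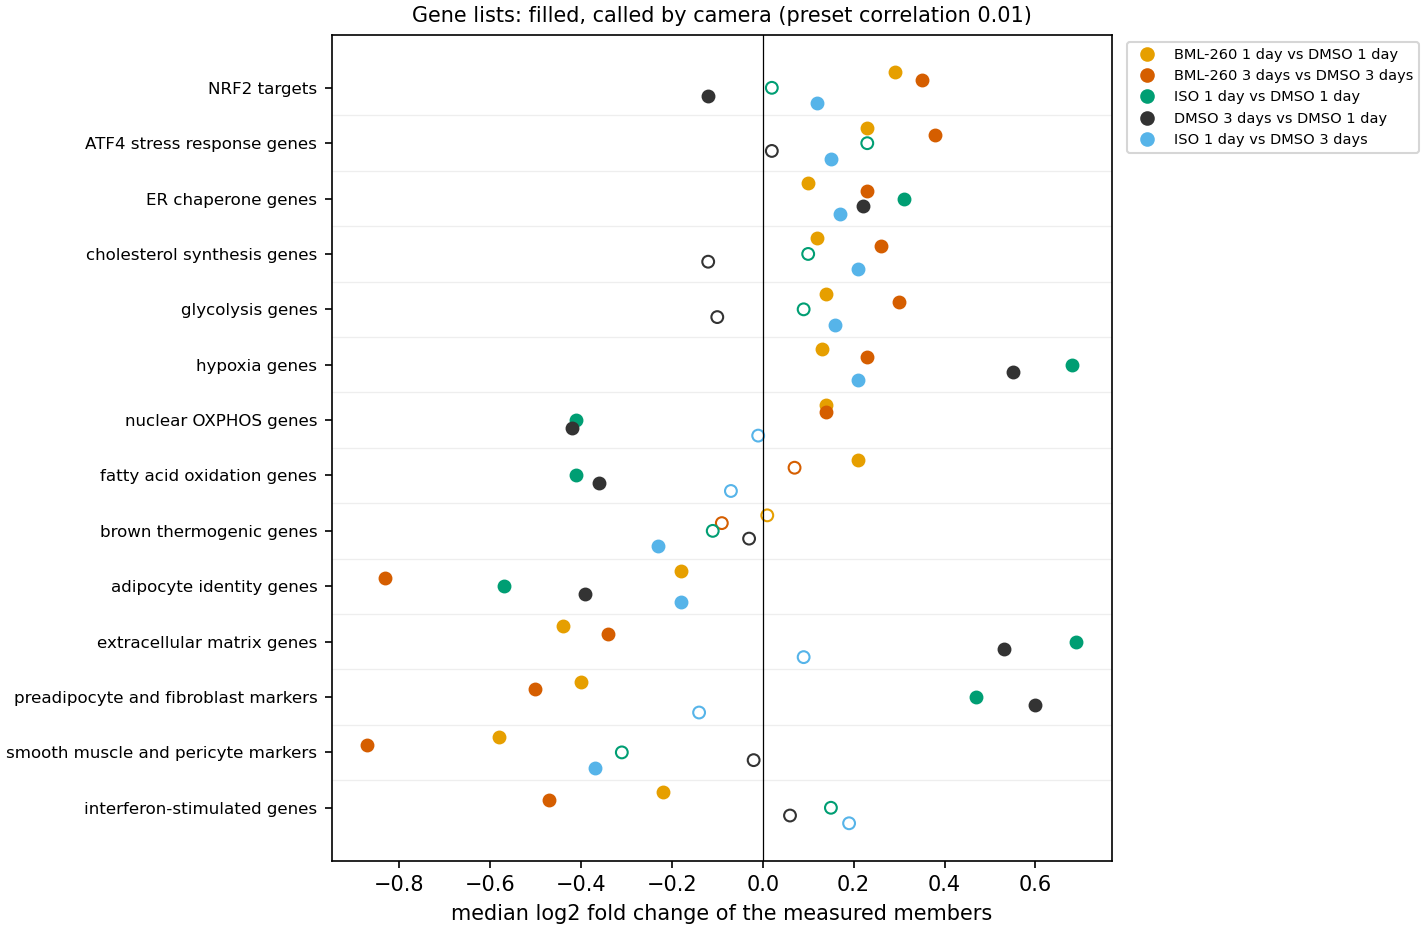
Median log2 fold change of the measured members of 14 gene lists (horizontal axis) in 5 comparisons, 1 point each, filled where camera called the list with its preset correlation of 0.01. OXPHOS and extracellular matrix genes stand at -0.41 and 0.69 with ISO against DMSO at 1 day, and at -0.42 and 0.53 for DMSO at 3 days against 1 day.

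BML-260 and ISO were last set against each other, both at the listed 1 day. Elovl3 was 2.72-fold higher with BML-260 (log2 1.45, SE 0.11) at 30.5 ± 3.6 CPM against 11.2 ± 0.62 CPM, and Ucp1 was lower, at 13.9 ± 2.0 CPM against 24.8 ± 1.8 CPM (SD, n = 2 each; log2 -0.83, SE 0.10, edgeR adjusted p = 1.7e-07). Also higher with BML-260 were Lrrc39 at 1.54, the glutathione transferase Gsta4 at 1.47, Osgin1 at 1.41 and Nabp1 at 1.40, and lower were Itga11 at -2.59, Nr1d1 at -2.24, Prg4 at -2.10, the procollagen protease Adamts2 at -2.10 and Sncg at -2.04. The 2 groups differed in 6753 genes, 3288 higher and 3465 lower with BML-260, of which 613 had an absolute log2 fold change of at least 1. With upper-quartile scaling the balance turned, to 3821 higher and 2987 lower. With BML-260 at 3 days in its place, 2499 genes differed from ISO. Nr1d1 at -0.19, Osgin1 at 0.10 and Nabp1 at 0.10 were then not called, Prg4 was at -0.57, Itga11 and Adamts2 were at -1.03, and Ucp1 turned to 0.36 higher with BML-260 (edgeR adjusted p = 0.00461).

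Camera called 14 lists between BML-260 and ISO at 1 day with its preset correlation, not all of which are described here. OXPHOS genes were higher with BML-260 than with ISO in 44 of 45 cases and lower in 0 (44 and 0 adjusted over the list alone). Cycs was at 0.96 (list median 0.54, camera adjusted p = 4.2e-21, and adjusted p = 0.13 with an estimated correlation). Fatty acid oxidation genes were higher in 20 of 22 cases and lower in 0 (20 and 0 adjusted over the list alone). Hadha was at 1.04 (for the list camera adjusted p = 1.7e-11, and adjusted p = 0.13 with an estimated correlation), and NRF2 targets were higher in 16 of 20 cases and lower in 2 (16 and 2 adjusted over the list alone; camera adjusted p = 3.7e-06, and adjusted p = 0.13 with an estimated correlation). Extracellular matrix genes were lower in 22 of 23 cases and higher in 0 (22 and 0 adjusted over the list alone). Col3a1 was at -2.02 and Col1a1 at -1.79 (list median -1.03, camera adjusted p = 3.3e-16, and adjusted p = 0.13 with an estimated correlation). Hypoxia genes were lower in 10 of 14 cases and higher in 1 (10 and 1 adjusted over the list alone; Pfkfb3 at -1.27; camera adjusted p = 6.4e-05, and adjusted p = 0.13 with an estimated correlation), and proliferation genes lower in 18 of 24 cases and higher in 0 (19 and 0 adjusted over the list alone; Aurkb at -0.57; camera adjusted p = 1.8e-06, and adjusted p = 0.13 with an estimated correlation). With BML-260 at 3 days against ISO the differences were smaller, with Cycs at 0.46, Hadha at 0.42, Col3a1 at -0.69 and Col1a1 at -0.43, and list medians of 0.15 for OXPHOS, 0.11 for fatty acid oxidation and -0.39 for matrix genes. The direction of the hypoxia genes turned, to a median of 0.075 (camera adjusted p = 0.0495, and adjusted p = 0.18 with an estimated correlation). Adipocyte identity and ER chaperone genes, also called at 1 day, turned as well, to medians of -0.515 and 0.092. The cAMP and CREB early targets were lower in 10 of 19 cases and higher in 4 (11 and 4 adjusted over the list alone; Sik1 at -1.09; camera adjusted p = 0.042, and adjusted p = 0.13 with an estimated correlation), a call lost without ISO replicate 1 and without either 3-day library of BML-260. With the estimated correlation camera called 0 of 31 lists, and 10 had an unadjusted p under 0.05. Log2 fold changes between BML-260 and ISO at 1 day correlated with gene length at Spearman's rho of -0.228. With the length and GC trends removed camera called 14 lists.

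The effects of BML-260 and ISO at 1 day share their DMSO libraries, which alone makes them correlate. Their log2 fold changes correlated across genes with Pearson's r of 0.267 and Spearman's rho of 0.211, genes not being independent replicates, and in 20 simulations of unchanged groups with shared controls r averaged 0.508. The covariance was 0.0387, against 0.0203 in the simulations, which leaves 0.0184. Both called 568 genes upward, with 303 expected, and 434 downward, with 265 expected, while 595 genes were called in opposite directions, with 568 expected. These expected counts take the comparisons as independent and leave out the shared libraries. Without DMSO 1 day replicate 2 r was 0.429, and without BML-260 1 day replicate 1 it was 0.192. With ISO set against DMSO at 3 days, which shares no library with BML-260 against DMSO at 1 day, r was 0.177, and 195 of the 942 genes called in both went in opposite directions. ISO against DMSO at 1 day and time in culture with BML-260, 3 days against 1 day, also share no library, and their r was 0.702. The second of these also holds the change of the BML-260 effect between the times. BML-260 at 3 days and ISO, both set against DMSO at 3 days, had r of 0.614. Of the 2230 genes called in both, 83 went in opposite directions, with 539 expected under independence. These effects share the DMSO 3 days libraries, which alone makes them correlate, and no simulation was run for this pair.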

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

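In this part the tests of collection with the 3-day cultures, of a response to ISO in the same genes as time in culture and of a smaller share of adipocytes, and the removal of length and GC trends, were chosen only after the results were seen.

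The test of the difference between times singled out 1287 genes whose response to BML-260 at 3 days differed from that at 1 day, and 22 named genes among them. The log2 effect at 3 days minus that at 1 day was 1.16 for Lrp8, 0.98 for Ghrh, 0.97 for Pgp, 0.91 for Dusp8, 0.87 for Scand1, 0.86 for Atf3, 0.67 for Extl1, 0.51 for Acox2, 0.43 for Sncg and 0.34 for Cbr3. It was -1.26 for Adrb3, -1.24 for Metazoa_SRP, -1.08 for Prox1, -1.07 for C4b, -1.03 for Retn, -0.86 for Ccl2, -0.71 for Adipoq, -0.67 for Rasd1, -0.63 for Mb, -0.59 for Hp, -0.40 for Fabp4 and -0.29 for Ppargc1a. Each group holds 2 libraries, and without BML-260 1 day replicate 2 the difference of Metazoa_SRP was -0.45 (edgeR adjusted p = 0.404).

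The ISO libraries, listed at 1 day, lie on the side of the 3-day libraries on the first principal component, between those of DMSO and BML-260, while the third component sets them apart from DMSO at 3 days (-19.5 and -14.4 against 14.5 and 12.6). Over the 7051 genes that differ between BML-260 at 3 days and 1 day, the slope of ISO minus DMSO 1 day on that difference was 0.711, that of DMSO 3 days minus 1 day 0.515, and their ratio 1.38 (1.30 to 1.47 over single libraries). Removing the trends with gene length and GC left the ratio at 1.39, which argues against such trends as the cause. The difference between BML-260 at 3 days and 1 day also holds the change of the BML-260 effect between the times, so the slopes do not measure time alone. Collection of the ISO cultures with the 3-day cultures is a candidate explanation, though a ratio above 1 leaves an excess that collection alone would not give. A response to ISO in the same genes cannot be told apart from it, since ISO minus DMSO 3 days correlated with the same difference at r of 0.29 and the labels give 1 ISO group.

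Adipocyte identity genes fell with BML-260 at 3 days, by a median of 0.83 on the log2 scale, though 3 of 20 rose. With an estimated correlation camera did not call the list (adjusted p = 0.27). A smaller share of adipocytes would by itself raise the markers of other cells, and 9 of 11 preadipocyte and fibroblast markers fell, with a median of -0.50 (-0.593 to -0.417 over single libraries). This cannot decide the question. Such markers also fell with BML-260 at 1 day and are also expressed in cultures of adipocytes, so their fall could hide a changed share. With the length and GC trends removed the median of the identity genes was -0.81 (-0.857 to -0.768 over single libraries; camera adjusted p = 9.03e-07), so these trends may account for little of it. An effect of BML-260 on these genes stays open as a hypothesis, since it was found and tested on the same libraries.

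At 1 day nuclear genes of oxidative phosphorylation (OXPHOS) rose and extracellular matrix genes fell with BML-260. With the length and GC trends removed the OXPHOS median went from 0.14 to 0.10 (0.0732 to 0.122 over single libraries; camera adjusted p = 3.99e-06), a narrow margin over 0.071, the bound set before the test. The matrix median went from -0.44 to -0.42 (-0.475 to -0.331 over single libraries; camera adjusted p = 5.31e-12). Upper-quartile scaling, which does not rest on the few most abundant genes, gave an OXPHOS median of 0.13 (0.0703 to 0.174 over single libraries; camera adjusted p = 1.22e-08). A response to BML-260 may underlie both, as a hypothesis, and camera called neither list with an estimated correlation (adjusted p = 0.19 and 0.17). Most preadipocyte and fibroblast markers and most smooth muscle and pericyte markers also fell at 1 day, and a changed share of cells was not tested for this pattern.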

How the results depend on the processing

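Only after the results were seen were these tests chosen: DMSO at 3 days as the control of ISO for named genes and lists, BML-260 at 3 days in place of 1 day against ISO, and removal of length and GC trends. Most named genes were picked for large changes or small p, which favours keeping a call. Over all 2727 genes called at 1 day DESeq2's Wald test kept 1732 in the same direction and limma-voom 2630. For the difference between times they kept 691 and 1241 of 1287. Of 791 results for named genes and list members, 785 kept direction and side of the threshold with DESeq2's size factors, 778 with upper-quartile scaling, 781 with no filter, 684 with at least 10 CPM in 2 libraries (96 had no value), 705 with DESeq2 (41 had none), 784 with limma-voom, 763 with only the groups compared (14 had none) and 782 with a replicate block. Of 78 list calls the same settings that apply kept 78, 76, 77, 66 and, with the block, 75, removal of length and GC trends kept 74, and an estimated correlation kept 0. The splits into higher and lower calls turned with the scaling. Upper-quartile scaling gave 1216 and 1423 for BML-260 at 1 day, 2077 and 3313 at 3 days, 2588 and 3831 for ISO, 470 and 807 for the difference between times, 3821 and 2987 for BML-260 against ISO and 2409 and 2844 for DMSO over time. DESeq2's size factors gave 2957 and 2518 for BML-260 at 3 days and 731 and 624 for the difference, and only the groups compared gave 1190 and 1265 for BML-260 at 1 day, 3005 and 2853 at 3 days, 926 and 622 for the difference and 2721 and 2827 for DMSO over time.

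For the counts at 1 day and for the difference between times, DESeq2 gave 1746 and 721 genes and an adjusted p under 0.01 gave 1543 and 527. An absolute log2 fold change of at least 1 left 98 genes for BML-260 at 1 day, 437 at 3 days, 573 for ISO, 68 for the difference between times, 613 for BML-260 against ISO and 249 for DMSO over time, as stricter thresholds must. The estimated correlation left 0 lists in each of the 6 comparisons, no filter gave 14 lists for ISO, and over genes called in either comparison r was 0.616 between the times of BML-260 and 0.304 between BML-260 and ISO. The cause was not tested for the tool, the filter and the correlation.

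With DMSO at 3 days as control ISO changed 3027 genes. The log2 values that turned in sign and were called were Cidea -0.36, Pdk4 -0.49, Hspe1 0.16, Lrrc32 -0.26, Fbn1 -0.16, Agt 0.30 and Tagln -0.38. Those that turned but were not called included Itga11 -0.049, Srebf1 0.13, Dgat1 0.03, Lipe 0.10, Hilpda -0.075 and Cpt2 0.019. The same held for Parp14 -0.11, Hspd1 0.072, Hspa1b 0.045, Dhcr7 0.054, Phlda3 0.165, Pdgfra -0.14, P2rx5 0.069, Dusp10 0.11 and Kdm3a -0.11. The median of the fibroblast markers turned to -0.14, that of the OXPHOS genes kept its sign at -0.013, and camera called neither list. With BML-260 at 3 days against ISO, 2499 genes and 23 lists were called, and the medians of adipocyte identity (-0.515), ER chaperone (0.092) and hypoxia genes (0.075) reversed. Both alternatives exchange a 1-day group for a 3-day group, and beyond that the cause was not tested.

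Leaving out 1 library, with the lone one assumed to vary like other groups, gave 1262 to 2922 genes for BML-260 at 1 day (1262 without DMSO 1 day replicate 2, 1733 and 1804 without BML-260 1 day replicate 1 and 2), 3785 to 5544 at 3 days, 4619 to 6367 for ISO, 5236 to 6796 for BML-260 against ISO and 3843 to 5433 for DMSO over time. The difference between times had 661 to 1410 (661 and 784 without DMSO 3 days replicate 1 and 2, 670 without DMSO 1 day replicate 2, 769 without BML-260 3 days replicate 1). Lists called ran from 17 to 19 for BML-260 at 1 day, 15 to 17 at 3 days, 9 to 13 for ISO, 6 to 8 for the difference, 12 to 14 for BML-260 against ISO and 10 to 12 for DMSO over time. The correlation ran from 0.364 to 0.425 between times and from 0.192 (without BML-260 1 day replicate 1) to 0.429 (without DMSO 1 day replicate 2) with ISO. Of the 791 results 100 lost a call in some such fit, 18 gained one and 0 reversed, and the cause was not tested. At these depths the simulated changes of 0.5 on the log2 scale were found in 87% to 98% of the changed genes, all of at least 10 CPM. Smaller changes, and changes of less abundant genes, were not simulated.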

Other observations

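The tests in this part, on clock genes and time of collection, were chosen only after the results were seen.

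A list of circadian clock genes, 19 of them measured, was drawn up after Nr1d1 and Per1 stood among the most raised genes. ISO against DMSO at 1 day raised 14 and lowered 2, DMSO at 3 days against 1 day raised 12 and lowered 2, and BML-260 at 3 days against 1 day raised 12 and lowered 1, by edgeR's test. Nr1d1 stood at 2.18, 1.60 and 2.05 in these comparisons on the log2 scale, Per1 at 1.60, 1.09 and 1.69, and Arntl, which peaks against them, at -1.32, -0.47 and -0.29, the last of which was not called (adjusted p = 0.062). With BML-260 against DMSO the list had 3 up and 2 down at 1 day, and 8 up and 4 down at 3 days. ISO still differed from DMSO at 3 days, with 7 up and 1 down, Nr1d1 at 0.58, Per1 at 0.51 and Arntl at -0.85. Of the 14 clock genes called for DMSO over time, 9 were called in the same direction both for ISO against DMSO at 1 day and for BML-260 over time. Nr1d1 and Per1 were among them. ISO against DMSO at 1 day and DMSO over time share the DMSO 1 day libraries, which alone makes them correlate. The list was also drawn up from these data, so this count does not show a cause. Time of collection cannot be told apart from an effect of time in culture or of ISO, since the labels give no hour of collection.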
